A study of Rattus norvegicus with 8 samples.

How the data were processed

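The data are the values of 8 Affymetrix Rat Genome 230 2.0 arrays, a 3'-biased expression array in which a gene is read by 1 or more probe sets. Each array was hybridised with labelled RNA from the brain of an adult male Wistar rat, 48 hours after an injection into the striatum, per the labels. Labelled RNA was made with either of a pair of kits, per the study's design text, and which array had which kit is not given in the sources used here. The deposited values are intensities on a linear scale, read from scans with the GCOS software per the submitters' processing notes. The design text also describes GC-RMA and GeneSpring normalization, and the labels say that the GeneSpring values were not supplied. Which algorithm made the deposited intensities is not stated per the labels. The values themselves show that each array had been scaled: with 2% of the values trimmed at each end, the mean lay between 100.021 and 100.023 on every array. Detection calls were not used here.

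Array columns were assigned to samples through the sample names, and no column belonged to another sample. Of 31099 probe sets, 57 are controls and were left out of the tests. The platform annotation names 1 gene symbol for 20826 of the others, several for 436 and none for 9780, and symbols were checked against a RefSeq table through the gene number, which changed 0 of them. A gene was represented by the probe set with a single symbol and the highest mean. No genome build is named with the values, so no coordinates are given.

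Intensities were turned into log2(intensity + 16). Array medians on this scale lay between 5.74 and 5.85, a span under the limit of 0.2 that was set for leaving the arrays as deposited, so no further normalization was made. Fold changes are on this scale, which understates the change of dim probe sets. Probe sets with a mean above the 40th percentile, an intensity of about 26.0, were tested, which left 18625 probe sets and 10539 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided, no block), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Errors of single genes are limma standard errors or 95% confidence intervals. The number of arrays limits the precision: the 95% interval of a log2 fold change reached 0.231 to either side of the estimate for the median probe set.

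Gene lists, 32 in number, were fixed before the data were examined, and 29 had the minimum of 5 tested members. They were tested with limma's camera with a preset correlation of 0.01 between genes. An estimated correlation and fry, a rotation test of whether a list's genes move on balance one way, were run as alternatives. A list's level on an array is the mean over its genes of the log2 level after setting each gene's mean over the 8 arrays to 0. Levels and array measures were compared between groups by exact two-sided permutation tests, whose smallest possible p with 4 against 4 arrays is 0.0286.

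The genes named were set by a rule fixed before the data were examined: the 12 genes with the largest change each way among those past the threshold with separated groups, the 3 members with the smallest p of each list whose member count is given, a fixed set of genes, and, where fewer than 5 genes passed in a direction, the 5 with the smallest p in that direction. Of the fixed set, Tlr9 and Tlr3 are not named by any single-symbol probe set in the annotation used here.

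The scripts were tested on simulated data with the fitted means of the 18625 probe sets. SDs were drawn from the variance distribution that limma fitted, and the noise was independent between probe sets. Where 200 probe sets were changed, 69.5% of these were recovered at 1.5-fold and 99.5% at 2-fold, with 10 wrong calls in each case. At 1.25-fold 0% were recovered with 0 calls, and 0 calls were made with no change. These shares do not carry over to genes that vary more or vary together. The standard error was 0.38 for Ifit3 and 0.54 for Irf7, and the estimated correlation between interferon-stimulated genes was 0.78. For the list tests, 50 simulated sets gave the 46 interferon-stimulated genes a shift per array that they shared but that had nothing to do with the groups. Camera with the preset correlation called that list in 66% of the sets, and camera with an estimated correlation and fry in 2% each.

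Alternatives fixed before the data were examined were pseudocounts of 1 and 64, quantile normalization, median centring, no level filter or one at the 60th percentile, other variance settings, array weights, the methods' t-test, the replicate number as a block, leaving out each array, and the mean of a gene's probe sets. Covariates for spike-in level and for the beta-actin 3' to 5' difference, leaving out both arrays of a number, and leaving out PBS replicates 3 and 4 together were added after the data had been seen.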

Results

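Expression was measured in brain tissue of adult male Wistar rats after stereotaxic injection into the striatum, the large input nucleus of the basal ganglia. For 1 group of 4 arrays the striatum had received 5 µl with 50000000 particles of a baculovirus vector. Baculoviruses infect insects and are used as gene transfer vectors because they enter mammalian cells without replicating there. The vector had been inactivated with ultraviolet light of 254 nm for 1 hour. For the other group of 4 arrays the striatum had received 5 µl of phosphate-buffered saline (PBS), and tissue was taken 48 hours after injection. Intensities of 18625 probe sets for 10539 genes were tested, and arrays correlated with each other at r between 0.970 and 0.986 across them. No 2 arrays held identical values. The design text mentions 7 rats and PBS injection into the contralateral side, and the labels do not tie an array to a rat. If all 8 arrays came from these 7 rats, some of them share an animal. The p-values therefore measure the spread between these samples, not between independent animals.

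The comparison asked how brain tissue responds to the inactivated vector beyond the response to the injection itself. No probe set passed an adjusted p of 0.05 in limma, with 0 higher and 0 lower after inactivated baculovirus. At an unadjusted p under 0.05, 468 probe sets were higher and 786 lower, against 931.25 expected by chance in both directions together. The methods' t-test also gave 0 probe sets after Benjamini-Hochberg adjustment, and 0 at its unadjusted threshold with at least a 2-fold change. Only 24 probe sets differed by 1.5-fold or more between group means and 2 by 2-fold or more. A probe set of the choroid plexus gene Ttr was among the latter through PBS replicate 4 alone. It was at 47.7 there and between 1563 and 1968 on the other arrays. The groups did not overlap for 719 probe sets, 3.86% of those tested, where chance gives 2.86%.

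The lowest adjusted p belonged to Spock3, which encodes a secreted proteoglycan of the testican family. Its intensity was 175 ± 12.3 after inactivated baculovirus and 266 ± 20.3 after PBS (SD, n = 4 each). Its log2 fold change was -0.56 (95% interval -0.74 to -0.38, limma adjusted p = 0.272). The next genes by p with lower means were Kcnab1, a potassium channel beta subunit, at -0.39 ± 0.07 (log2 fold change ± SE), Vma21, an assembly factor of the vacuolar proton pump, at -0.44 ± 0.09, Tmem263 at -0.37 ± 0.08 and Osbpl8, an oxysterol-binding protein, at -0.41 ± 0.09. Both other probe sets of Vma21 had the same direction, and 1 of the 2 other probe sets of Tmem263 had the opposite one. Among genes with higher means, Kcnip3, a calcium-binding partner of potassium channels, came first at 0.35 ± 0.07, with 506 ± 31.1 against 394 ± 18.5 in intensity (SD). It was followed by Syngr1, a synaptic vesicle protein, at 0.52 ± 0.12, Dnajb5, a co-chaperone, at 0.61 ± 0.14, Pura, a nucleic acid-binding protein, at 0.44 ± 0.11, and Bgn, which encodes the matrix proteoglycan biglycan, at 0.47 ± 0.12. The other probe set of Syngr1 had the opposite direction. None of these 10 genes passed. The limma adjusted p was 0.686 for each of them apart from Spock3. This ranking takes 1 probe set with a single symbol per gene. Among all probe sets with higher means, the smallest p belonged to a probe set outside the ranking. It measured 43.6 ± 6.27 against 18.0 ± 6.25 in intensity (SD, n = 4 each) and did not pass (limma adjusted p = 0.396).

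**Figure D1:**
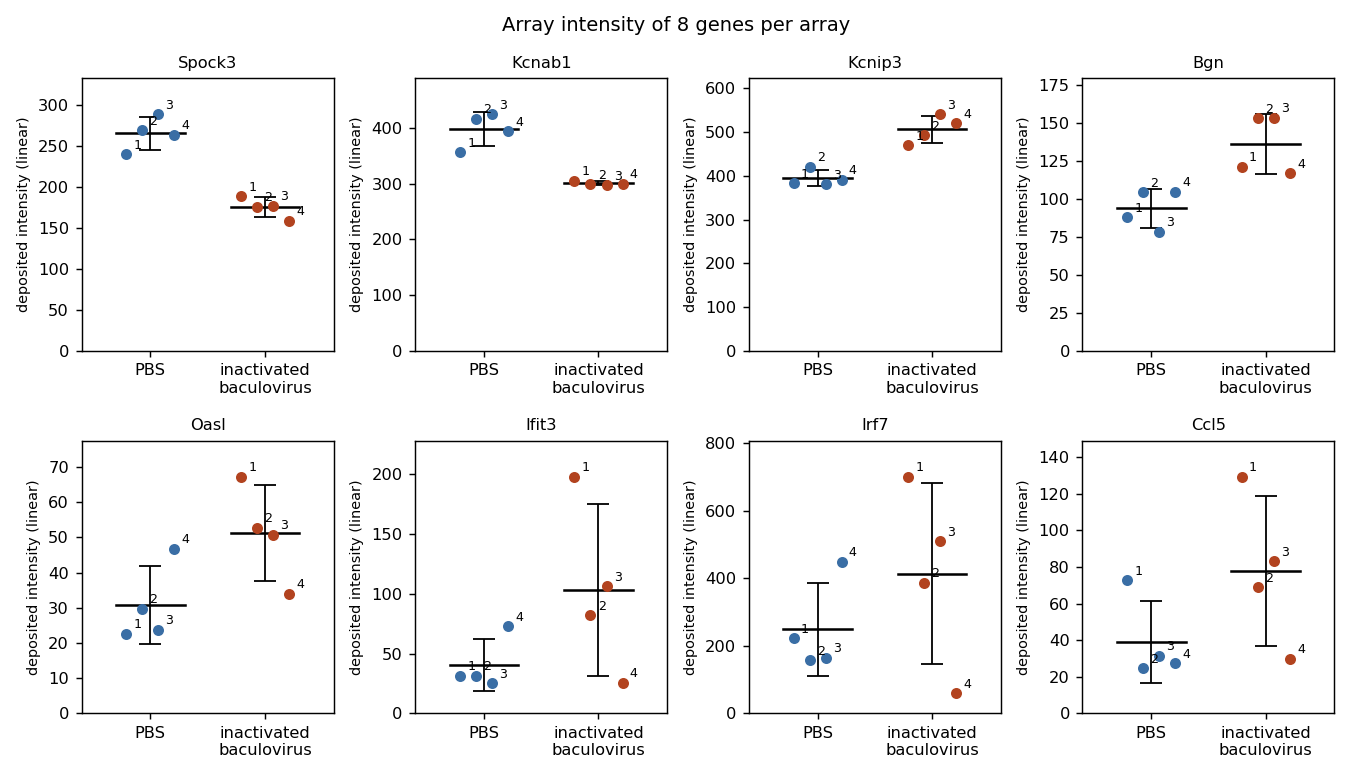
Deposited intensity (linear scale) of 8 genes on the 4 PBS arrays (blue) and the 4 inactivated baculovirus arrays (red), with replicate numbers, group mean (long line) and 1 SD (bars). Spock3 and Kcnab1 lie lower and Kcnip3 and Bgn higher on all 4 baculovirus arrays than on any PBS array, while for Irf7 baculovirus replicate 4 is the lowest of the 8 arrays and PBS replicate 4 the third highest, and none of the 8 genes passed adjustment.

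Interferon-stimulated genes, the antiviral program that cells switch on through the interferon receptors, had a higher mean after inactivated baculovirus for all 46 members tested, by 0.31 on the log2 scale on average. None passed over all probe sets, 0 passed when adjusted over the list alone, and 4 were under an unadjusted p of 0.05. Oasl, an antiviral protein of the oligoadenylate synthetase family, measured 51.2 ± 13.6 against 30.7 ± 11.1 (SD, n = 4 each). Ifit3, an inhibitor of viral translation, measured 103 ± 71.7 against 40.3 ± 21.8. Tor3a had a log2 fold change of 0.36 ± 0.13 (SE), and Irf7, the transcription factor that amplifies the interferon response, one of 0.43 ± 0.54. Camera with the preset correlation called the list higher (adjusted p = 4.03e-08). The call was lost with an estimated correlation of 0.78 between its genes (adjusted p = 0.799 with an estimated correlation) and with fry (adjusted p = 0.774). An exact permutation test of the list's level gave p = 0.371, and 3 of the 4 baculovirus arrays lay above the PBS mean. Baculovirus replicates 1, 2 and 3 stood at 0.73, 0.18 and 0.33 and replicate 4 at -0.61, while PBS replicates 1 to 3 stood at -0.18, -0.39 and -0.23 and replicate 4 at 0.18. Without baculovirus replicate 1, 35 of 47 members had a higher mean, by 0.11 on average, and the camera adjusted p was 0.253. Without baculovirus replicate 4 the average was 0.57.

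**Figure D2:**
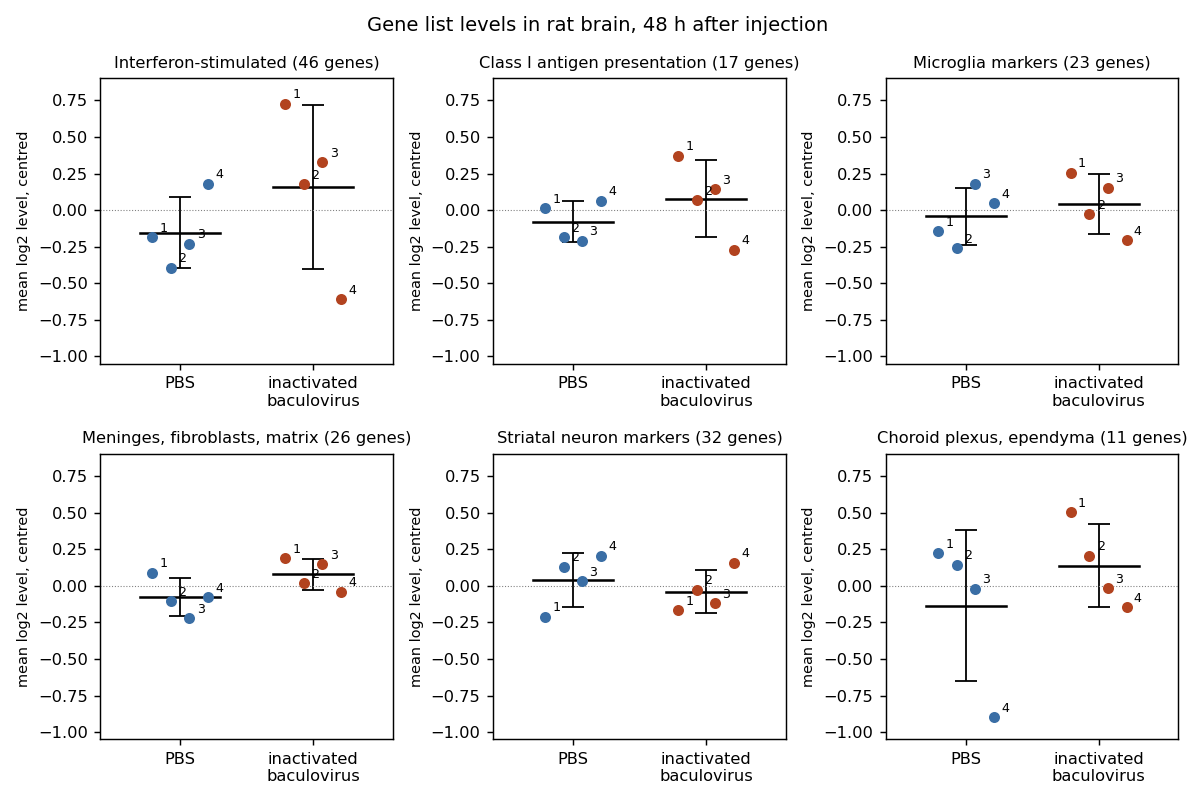
Level of 6 gene lists on each array, as the mean centred log2 intensity of its genes (PBS blue, inactivated baculovirus red), with replicate numbers, group mean (long line) and 1 SD (bars). In each list at least 1 array of one group lies within the range of the other, and the interferon level spans 0.73 to -0.61 within the baculovirus group.

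The level of the interferon list followed a measure of RNA quality and labelling across the 8 arrays, the log2 difference between the 3' and 5' probe sets for beta-actin. Pearson's r was -0.890 (exact permutation p = 0.00357, Benjamini-Hochberg 0.0179 over 5 array measures) and Spearman's rho -0.929 (exact permutation p = 0.00223, Benjamini-Hochberg 0.0112). Without baculovirus replicate 4 and PBS replicate 2, the arrays farthest from the median difference, r was -0.758. The actin difference itself did not separate the groups, with 0.504 ± 0.162 after inactivated baculovirus and 0.520 ± 0.0998 after PBS (SD, n = 4 each, exact permutation p = 0.886). The corresponding difference for GAPDH gave r = -0.675 (exact permutation p = 0.0672) and rho = -0.619 (exact permutation p = 0.115), and that for hexokinase r = 0.21 (exact permutation p = 0.608) and rho = 0.357 (exact permutation p = 0.389).

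**Figure D3:**
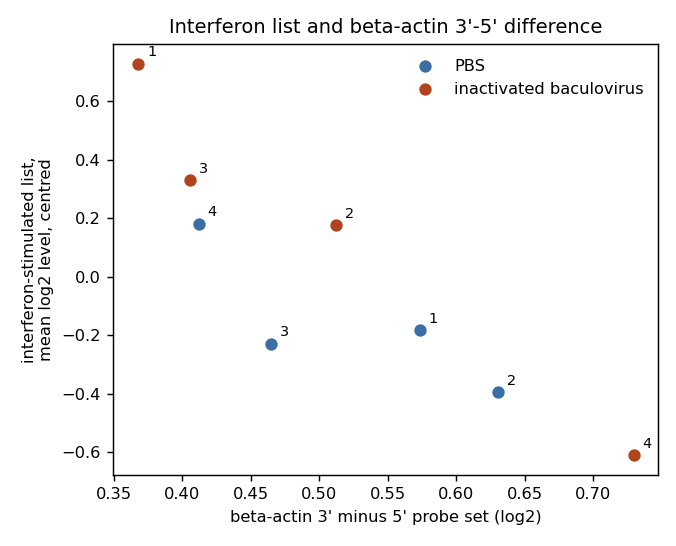
Level of the interferon-stimulated list (mean centred log2 intensity) against the log2 difference of the beta-actin 3' and 5' probe sets, one point per array with its replicate number (PBS blue, inactivated baculovirus red). Arrays with a larger difference had a lower interferon level, r = -0.890 over 8 arrays, and both groups spread along the relation.

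Other immune lists had mostly higher means without a call in the main setting. Of 17 tested genes of class I antigen presentation, which show peptides to T cells, 15 were higher and 2 lower (camera adjusted p = 0.0632). With quantile normalization this list was called higher (camera adjusted p = 0.0259). The members with the smallest p were Canx at -0.15 ± 0.08 (log2 fold change ± SE), Calr at 0.30 ± 0.19 and the immunoproteasome subunit Psmb9 at 0.42 ± 0.26. Canx and Calr are general chaperones of the endoplasmic reticulum. Calr was at 505 on PBS replicate 3 and between 1041 and 1162 on the other arrays of both groups, which overlapped apart from that array. Class II antigen presentation had 9 members higher and 2 lower (adjusted p = 0.21), with RT1-Ba at 0.35 ± 0.22, RT1-Da at 0.37 ± 0.26 and RT1-DMa at 0.15 ± 0.12. Chemokines and cytokines had 16 higher and 6 lower (adjusted p = 0.0709). Ccl5, which attracts T cells and monocytes, measured 77.8 ± 41.0 against 39.1 ± 22.5 (SD, n = 4 each), Tnfsf10 had a log2 fold change of 0.30 ± 0.14 and Cxcl14 of 0.21 ± 0.11. Complement and coagulation genes had 13 higher and 2 lower (adjusted p = 0.135), with C3 at 0.29 ± 0.15, C1qc at 0.20 ± 0.15 and Serping1 at 0.25 ± 0.21. No member of these 4 lists passed over all probe sets or when adjusted over the list alone. Without baculovirus replicate 1 the members higher and lower were 13 and 4 for class I, 6 and 5 for class II, 14 and 8 for chemokines and 8 and 7 for complement, and the mean log2 fold changes of 0.16, 0.16, 0.17 and 0.11 became 0.06, 0.06, 0.09 and 0.04. Without baculovirus replicate 4 they were 0.27, 0.33, 0.30 and 0.22. Without PBS replicate 2 class II had 6 higher and 5 lower and complement 9 and 6, with means of 0.06 and 0.05, and without baculovirus replicate 3 the means were 0.07 and 0.08. The levels of the class II, complement and chemokine lists followed the beta-actin difference across the 8 arrays, with r = -0.928, -0.921 and -0.901 and rho = -0.976, -0.929 and -0.929. Their exact permutation p values for r were 4.96e-05, 0.000322 and 0.00228 (Benjamini-Hochberg 0.00144, 0.00468 and 0.0105 over 29 lists), and r was -0.797, -0.782 and -0.780 without baculovirus replicate 4 and PBS replicate 2.

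Among markers of microglia, the resident macrophages of the brain, 19 of 23 had a higher mean and 4 a lower one (camera adjusted p = 0.171). Olfml3 stood at 0.28 ± 0.10 and the fractalkine receptor Cx3cr1 at 0.23 ± 0.11, while Sall1, a transcription factor of resting microglia, stood at -0.26 ± 0.12 (log2 fold change ± SE). The fixed genes Aif1 and Cd68, common stains for microglia and macrophages, stood at 0.15 ± 0.13 and 0.41 ± 0.32. Monocyte and macrophage markers had 15 higher and 3 lower (adjusted p = 0.173), with Vcan at -0.36 ± 0.12, Arg1 at -0.22 ± 0.12 and S100a6 at 0.23 ± 0.14. Of the 4 other probe sets of Vcan, 2 had the opposite direction. Of 36 T and NK cell markers on the array, only 9 were above the level filter, with 8 higher and 1 lower (adjusted p = 0.0709). They were led by Ccl5, also a member of the chemokine list, Cd4 at 0.24 ± 0.13 and Cd7 at 0.26 ± 0.14. Cd3e and Cd8a, which mark T cells, were below the level filter, at 14.4 ± 4.10 against 10.7 ± 4.19 and at 19.9 ± 8.33 against 11.6 ± 6.12 in intensity (SD, n = 4 each). Neutrophil, B cell and red cell lists had fewer than 5 members above the filter and were not tested. No member of the tested lists passed over all probe sets or when adjusted over the list alone. Without baculovirus replicate 1 microglia markers had 13 higher and 10 lower, and their mean log2 fold change turned from 0.09 to -0.00254, and it was 0.05 and 0.15 without baculovirus replicate 3 or 4 and 0.05, 0.02 and 0.16 without PBS replicate 1, 2 or 3. Monocyte and macrophage markers, at 0.11 on average, were at 0.03 and 0.20 without baculovirus replicate 1 or 4 and 0.04 without PBS replicate 2. Microglia and monocyte levels followed the beta-actin difference, with r = -0.903 and -0.928, rho = -0.905 and -0.976, and exact permutation p = 0.00253 and 0.000967 for r (Benjamini-Hochberg 0.0105 and 0.00561 over 29 lists). Without the same 2 arrays r was -0.870 and -0.941.

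Reactive astrocyte genes had 19 members higher and 6 lower (camera adjusted p = 0.21). Ptgs2 stood at -0.21 ± 0.11, S1pr3 at 0.30 ± 0.16 and the interferon-inducible chemokine Cxcl10 at 0.56 ± 0.31 (log2 fold change ± SE). The level of this list followed the beta-actin difference at r = -0.933 and rho = -0.952 (exact permutation p = 0.000595 for r, Benjamini-Hochberg 0.00561 over 29 lists), with r = -0.885 without the same 2 arrays. Its mean log2 fold change of 0.11 became 0.04 and 0.20 without baculovirus replicate 1 or 4 and 0.06 without PBS replicate 2. Gfap, the filament protein that rises in reactive astrocytes, measured 1671 ± 89.2 against 1647 ± 203 (SD, n = 4 each). Its log2 fold change was 0.03, with a 95% interval of -0.15 to 0.21, and turned to -0.00221 with median centring. General astrocyte markers had 7 higher and 10 lower (adjusted p = 0.399), with the bicarbonate transporter Slc4a4 at -0.14 ± 0.07, the glutamate transporter Slc1a2 at 0.12 ± 0.08 and Cldn10 at -0.11 ± 0.08. Oligodendrocyte and myelin genes had 8 higher and 12 lower (adjusted p = 0.411), with Tspan2 at -0.21 ± 0.10, Ugt8 at -0.23 ± 0.12 and Bcas1 at -0.11 ± 0.06. The mean of the oligodendrocyte list, -0.02, turned to 0.00717 without baculovirus replicate 4 and 0.0125 without PBS replicate 2, and ran from -0.04 to 0.0125 with 1 array left out, while that of the astrocyte list ran from -0.03 to -0.000939. Oligodendrocyte precursor markers had 3 higher and 7 lower (adjusted p = 0.0709), with Vcan, Ptprz1 at -0.17 ± 0.07 and Sox6 at -0.21 ± 0.11. The other probe sets of Slc4a4, Ugt8 and Sox6, 1 for each gene, had the opposite direction. No member of these 4 lists passed over all probe sets or when adjusted over the list alone.

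Markers of striatal projection neurons had a lower mean for 25 of 32 members and a higher one for 7, by -0.08 on the log2 scale on average. None passed over all probe sets or when adjusted over the list alone. Bcl11b, a transcription factor of these neurons, measured 310 ± 38.4 against 413 ± 63.6 (SD, n = 4 each), Meis2 had a log2 fold change of -0.28 ± 0.09 (SE) and Gad1, an enzyme of GABA synthesis, of -0.19 ± 0.07. For Bcl11b 1 of 2 other probe sets and for Gad1 the other probe set had the opposite direction. The fixed striatal gene Ppp1r1b, which encodes the dopamine signalling protein DARPP-32, stood at 0.06 with a 95% interval of -0.17 to 0.28. Camera with the preset correlation called the list lower (adjusted p = 0.00454), which was lost with an estimated correlation (adjusted p = 0.799) and with fry (adjusted p = 0.774). The exact permutation p of the list's level was 0.514, with 3 of 4 baculovirus arrays below the PBS mean. The camera call was also lost without baculovirus replicate 1 (adjusted p = 0.444) or 3 (0.0659) and without PBS replicate 2 (0.174) or 4 (0.312). The average log2 fold change was -0.04, -0.05 and -0.14 without baculovirus replicate 1, 3 or 4, and -0.16, -0.05 and -0.02 without PBS replicate 1, 2 or 4.

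Genes of meninges, fibroblasts and extracellular matrix had a higher mean for 22 of 26 members and a lower one for 4. Bgn measured 136 ± 19.8 against 93.7 ± 12.8 (SD, n = 4 each) and was the 1 member past the threshold when adjusted over the list alone (adjusted p = 0.0354), while 0 passed over all probe sets. Col4a2, a collagen of basement membranes, stood at 0.34 ± 0.10 and Igfbp2 at 0.25 ± 0.10 (log2 fold change ± SE). Camera with the preset correlation called the list higher (adjusted p = 8.62e-05), which was lost with an estimated correlation (adjusted p = 0.799) and with fry (adjusted p = 0.774). The exact permutation p of its level was 0.143, with all 4 baculovirus arrays above the PBS mean. Endothelial and mural genes had 20 higher and 8 lower (camera adjusted p = 0.173), with Tie1 at 0.28 ± 0.11, Ly6e at 0.28 ± 0.13 and Kdr at 0.26 ± 0.13. Choroid plexus and ependyma markers had 9 higher and 2 lower (camera adjusted p = 0.118), with Folr1 at 0.45 ± 0.26, Steap1 at 0.30 ± 0.17 and Aqp1 at 0.22 ± 0.13. No member of these endothelial and choroid lists passed over all probe sets or when adjusted over the list alone. The choroid level was -0.90 on PBS replicate 4 and between -0.02 and 0.22 on the other PBS arrays. Without PBS replicate 4 this list had 6 members higher and 6 lower, and its mean log2 fold change of 0.27 became 0.00883, while it was 0.15 without baculovirus replicate 1. The endothelial mean of 0.09 was 0.13 without baculovirus replicate 4.

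The remaining fixed genes did not pass either. The adaptor Myd88, which relays signals from Toll-like receptors, measured 56.4 ± 11.3 against 57.9 ± 8.25, and Irf3, a transcription factor activated by viral nucleic acids, 165 ± 12.8 against 159 ± 7.86 (SD, n = 4 each). Ifnb1, which encodes interferon beta, was below the level filter at 3.82 ± 1.03 against 2.79 ± 1.62. The neuronal marker Rbfox3 stood at 0.13 ± 0.09 and the myelin gene Mbp at -0.03 ± 0.08 (log2 fold change ± SE), and both other probe sets of Mbp had the opposite direction. Hbb, a haemoglobin chain that reports blood in the tissue, varied within both groups, with 331 ± 316 against 178 ± 209 (SD).

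Spike-in controls, bacterial and phage transcripts added to each hybridisation in fixed amounts, had lower means on baculovirus arrays and so accompany each gene difference given above. On the log2 scale BioB was at 5.10 ± 0.47 on baculovirus arrays and 6.04 ± 0.18 on PBS arrays, BioC at 6.49 ± 0.51 and 7.38 ± 0.16, BioD at 8.19 ± 0.41 and 8.95 ± 0.13, and Cre at 10.1 ± 0.19 and 10.5 ± 0.10 (SD, n = 4 each). The exact permutation p was 0.0286, the smallest that 4 against 4 arrays allow, for BioB, BioD and Cre and 0.0571 for BioC. Over the 4 controls the mean was 7.47 ± 0.39 on baculovirus arrays and 8.23 ± 0.14 on PBS arrays (exact permutation p = 0.0286). After Benjamini-Hochberg adjustment over 7 control measures the values were 0.0667 and 0.1. With this smallest possible p the 4 controls alone could not have passed among 7 measures, so the adjustment does not count against the difference. The 3 leading principal components of the tested probe sets held 25.2%, 19.9% and 16.9% of the variance. The exact permutation p between the groups was 0.143, 0.857 and 0.943, which with 4 against 4 arrays does not show that the groups are alike. On the first component baculovirus arrays lay between -9.72 and -5.80. PBS replicates 1 to 4 lay at 13.8, 0.57, 24.9 and -11.3 on it.

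The numbers of genes and lists called depended little on single arrays for the first and strongly for the second. Leaving out any array kept 0 probe sets past the threshold each way, and leaving out both replicate 4 arrays, chosen after the data had been seen, gave 7 higher and 0 lower. The 3 camera calls became 16 without baculovirus replicate 4, 8 without PBS replicate 3, 6 without PBS replicate 4, 5 without PBS replicate 1 and 1 without baculovirus replicate 1.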

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

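In 212 groups of 4 arrays examined, over named genes, list levels and array measures, 10 held an array whose gap to the nearest of the others took most of the group's range. Chance gives 1 in 20, or about 10.6, so the number of such groups is what chance alone would give, and no pattern among them was weighed. The list levels are on the centred log2 scale and gene values are intensities.

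Calr, a chaperone of the endoplasmic reticulum, was at 505 on PBS replicate 3 and between 1041 and 1089 on the other PBS arrays. RT1-Da, a class II gene, was at 135 on PBS replicate 2 against 238 to 259 on the others. Arg1 was at 49.5 on baculovirus replicate 4 against 36.6 to 37.2. On baculovirus replicate 1, Tmem263 was at 229 against 190 to 196 and Bcas1 at 691 against 720 to 721.

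The complement and coagulation list was at -0.255 on PBS replicate 2 and between -0.02 and 0.03 on the other PBS arrays, while baculovirus replicate 4 was at -0.260. Endothelial and mural genes were at -0.104 on baculovirus replicate 4 against 0.09 to 0.10. NF-kB targets and adhesion genes were at 0.117 on baculovirus replicate 1 against -0.05 to -0.02. Cortical and hippocampal neuron markers were at 0.0779 on baculovirus replicate 3 against -0.04 to -0.03. Cholesterol synthesis genes were at 0.0436 on baculovirus replicate 4 against values within 0.00154 of 0.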

How the results depend on the processing

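Covariates and the removal of more than 1 array were chosen after the data had been seen. All counts of probe sets past adjusted p 0.05 were 0 under every setting, except that without both replicate 4 arrays 7 were higher, 6 of them at least 2-fold, and 0 lower (0 to 7 and 0 to 6 over all left-out arrays). The cause was not tested. Without an adjustment the split of 468 higher to 786 lower became 263 to 1085 with median centring and 425 to 881 with quantile normalization. The balance turned to 366 higher and 155 lower with the spike-in level as a covariate, 608 and 526 without baculovirus replicate 4, 341 and 337 without both replicate 2 arrays, and 1031 and 813 without both replicate 4 arrays. The intensities hold no background measure, so how far dim genes limit the counts is unknown.

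The 3 called lists were 4 with quantile normalization, 7 with median centring, 6 without a level filter and 9 with array weights. The count was 5 with the beta-actin difference as a covariate and 19 with the spike-in level as a covariate. It was 15 without PBS replicates 3 and 4, and 0 with an estimated correlation or fry. With arrays left out the count ran from 1 to 16. The interferon, meninges and striatal lists had adjusted p = 0.799 with an estimated correlation and 0.774 with fry. Both allow for the correlation between genes, and fry also asks another question, whether a list's genes move on balance one way. With 1 array or both arrays of a replicate number left out, adjusted p ran from 6.58e-46 to 0.434 for the interferon list, from 6.25e-08 to 0.0536 for the meninges list and from 9.01e-09 to 0.444 for the striatal list. Without PBS replicates 3 and 4 they were 2.67e-11, 0.0632 and 0.693, and ribosomal proteins, lower before, were called higher (0.00946). The cause of these changes was not tested. Robust variance was not run for lists, since camera has no such option.

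With the replicate number as a block, 8 lists and 0 probe sets passed. The numbers were not taken to pair the arrays, since the rule set beforehand asked for r over 0.1 in every same-numbered pair. Same-numbered arrays correlated between -0.00511 and 0.0160 in their deviations from the group means, and other pairs between -0.106 and 0.0750. Of the 8 arrays, 0 correlated best with their own number. Low correlations show no shared signal but cannot exclude that a number marks a rat.

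Of 65 tested named genes, 61 kept their direction in every setting that was run for single genes. The covariates and the removal of several arrays together were not run for single genes, so directions under them are unknown. The other variance settings, the methods' t-test and the replicate block leave the fold changes as they are and could not turn a direction. Mbp, at -0.03, was at 0.00846 with quantile normalization, 0.0544 with the mean of its probe sets, and between -0.098 and 0.0233 with single arrays left out. Gfap, at 0.03, was at -0.00221 with median centring and between -0.032 and 0.0911, Myd88, at -0.03, between -0.123 and 0.0619, and Ppp1r1b, at 0.06, between -0.0186 and 0.15 with single arrays left out.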

Other observations

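The tests of the beta-actin relation, the microglia share, both choroid plexus explanations and all counts over splits except that of gene lists were chosen only after the result was seen, as were Ttr and Slc17a7 as genes to name.

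Gene groups outside the immune and cell type lists differed little between inactivated baculovirus and PBS. The mean log2 fold change was 0.05 for immediate early genes, 0.07 for cell cycle genes, 0.06 for oxidative stress and metal response genes, 0.02 for cholesterol synthesis, and -0.00704 for ribosomal proteins, with camera adjusted p from 0.171 to 0.882. Pattern recognition genes stood at 0.10 (adjusted p = 0.295), JAK-STAT and cytokine receptors at 0.09 (0.147) and cortical and hippocampal neuron markers at -0.02 (0.522). For NF-kB targets (mean 0.00895), synaptic genes (0.00142), apoptosis genes (0.0235, median -0.00351), heat shock genes (0.0263) and oxidative phosphorylation genes (0.00541, median -0.00935), camera gave the direction lower while the mean lay above 0, with adjusted p from 0.538 to 0.998. With 1 array left out these means moved by over 1.5 times or turned, here given from the lowest to the highest with the replicate left out. This held for the immediate early (0.0127 without baculovirus 4 to 0.11 without PBS 4), cell cycle (0.02 without PBS 1 to 0.12 without PBS 3), oxidative stress (0.03 without baculovirus 1 to 0.10 without baculovirus 4), cholesterol synthesis (0.00274 without PBS 3 to 0.04 without PBS 4) and ribosomal (-0.05 without PBS 2 to 0.04 without PBS 3) lists. It also held for the pattern recognition (0.02 without baculovirus 1 to 0.20 without baculovirus 4), JAK-STAT (0.05 without baculovirus 1 to 0.13 without PBS 4), cortical and hippocampal (-0.05 without PBS 4 to 0.000529 without PBS 2) and NF-kB (-0.03 without baculovirus 1 to 0.04 without PBS 4) lists, and for the synaptic (-0.03 without PBS 3 to 0.03 without PBS 2), apoptosis (0.00089 without baculovirus 1 to 0.04 without baculovirus 4), heat shock (0.00274 without baculovirus 1 to 0.05 without PBS 1) and oxidative phosphorylation (-0.03 without baculovirus 4 to 0.05 without baculovirus 1) lists.

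Slc17a7, the vesicular glutamate transporter of cortical neurons, measured 454 on PBS replicate 3 and between 909 and 1270 on the other arrays. The list of 19 cortical and hippocampal neuron markers was not low there, with a level of 0.0125 on that array and -0.082 on PBS replicate 4, the lowest. Ttr, the transthyretin gene that choroid plexus expresses strongly, measured 47.7 on PBS replicate 4 and between 1563 and 1968 on the other arrays.

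The choroid plexus genes on PBS replicate 4 were weighed against a missing piece of tissue and a poor array. Of 11 tested choroid and ependyma markers, 7 were lowest on this array where 1.38 would be expected (exact one-sided binomial p = 9.92e-05). This p restates the pattern, since the array was picked for the low level of the same list and its members vary together, so choroid plexus missing from that tissue piece stays open. Ttr was the single gene at least 2 log2 units below all other arrays, a limit that dim genes reach less easily on this scale. Sostdc1 was at 19.5 against 107 to 317 on the other arrays and Folr1 at 31.1 against 77.9 to 155. Tmem212, at 66.6 against 45.3 to 78.5, was not low. The mean correlation of this array with the others exceeded the lowest of the 8 by 0.00635, against an SD of 0.00274, which argues against a poor array. No biological explanation was tested.

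The interferon list differed within the baculovirus group by 1.34 ± 0.11 (log2, SE over 46 genes) between replicates 1 and 4, and microglia markers by 0.46 ± 0.09 (23 genes). Microglia markers thus differed less between these arrays, by -0.874 ± 0.142. The arrays are the highest and lowest of the 8 on the interferon list itself, and the errors are over genes that vary together. This comparison therefore cannot decide on a different share of microglia, which stays open. With both replicate 4 arrays held out, their position along the group difference of the other 6, outside the immune lists, differed by -0.149. This lay below each of the 9 pairs that share neither array (0.00736 to 0.582, mean 0.219). It stayed within 1 SD of those pairs (0.173) from 0, the bound set beforehand. The low value was not particular to this pair. PBS replicate 4 gave -0.221, 0.04 and -0.159 with baculovirus replicates 1, 2 and 3. Baculovirus replicate 4 gave 0.11, -0.04 and 0.28 with PBS replicates 1, 2 and 3. The held-out positions therefore do not decide on an exchange of these arrays. The spike-in levels go with the labels, at 7.26 on baculovirus replicate 4 and 8.26 on PBS replicate 4 against PBS values from 8.09 to 8.41, but baculovirus replicate 1 was at 8.03 and tissue exchanged before hybridisation would leave them as they are, so exchanged and correct labels cannot be told apart. RNA integrity or labelling may contribute, since the relation to the beta-actin difference had an exact permutation p of 0.00357. GAPDH and hexokinase gave no p under 0.05. After Benjamini-Hochberg adjustment 9 of 29 lists followed the beta-actin difference, all with negative r. They were the interferon, class II, complement, chemokine, pattern recognition, microglia, monocyte, reactive astrocyte and oxidative stress lists. Some of these lists share members, such as Cxcl10 in the interferon, chemokine and reactive astrocyte lists. Their levels also varied together over the same 8 arrays, so they do not count as 9 separate results. A different strength of response in single animals was not tested and stays open.

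With the beta-actin difference as a covariate, the interferon list's mean log2 fold change was 0.26, where it was 0.31 without, and 15 members were under an unadjusted p of 0.05 in place of 4. Of them, 6 passed when adjusted over the list alone. With an estimated correlation the list gave p = 0.0748 (adjusted p = 0.528). Under the preset correlation 5 lists passed with this covariate. With the spike-in level as a covariate the mean was 0.98, 35 members were under an unadjusted p of 0.05, 32 passed over the list alone and the estimated correlation gave p = 0.0323 (adjusted p = 0.156), but this level nearly follows the groups.

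The spike-in controls were lower on baculovirus arrays, by -0.76 on the log2 scale on average. If hybridisation conditions lay behind the expression differences, baculovirus replicate 1, whose spike-in level of 8.03 was nearest to the PBS mean of 8.23, would sit with the PBS arrays. Held out against each PBS array, its mean position difference was 0.0318 ± 0.0869 (SE), which does not decide. Hybridisation and treatment cannot be told apart here, because the spike-in level nearly follows the groups. Each array was scaled to the same trimmed mean, so a difference in total signal or in the RNA hybridised would shift these controls too, and this was not tested.

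The 8 arrays split into 4 and 4 in 35 ways. With a real count of 0 probe sets past adjusted p 0.05, and 0 of them at least 2-fold changed, all 35 splits give as many by construction, so these counts of splits say nothing about chance. The highest counts in another split were 16 and 10. At an unadjusted p under 0.05, 9 of the 35 splits gave as many as the real 1254, with up to 2261. Camera with the preset correlation called 3 lists or more in 34 of the 35 splits, with up to 17. Chance cannot be excluded for the unadjusted and list counts. The 16 probe sets came from baculovirus replicates 1, 2 and 3 with PBS replicate 4 against the rest, the highest of 34 other splits. These are the 4 arrays with the highest interferon level, so this split points to a structure of the samples along that level, which was not tested. It is also the grouping of an exchange of the replicate 4 arrays, but it restates the pattern that raised that question and gives no support for it. The interferon list was called in 27 of the 35 splits.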
